A study of Homo sapiens with 6 samples.

How the data were processed

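RNA of the 6 libraries (2 each of TSC, ST and EVT) had been extracted with a column kit, converted to tagmented poly(A) libraries and sequenced. Per the labels, the authors demultiplexed the reads with bcl2fastq 2.20 and processed them with DRAGEN on GRCh38; the DRAGEN version, quantifier settings and annotation release were not given. The deposited tables hold expected counts that the authors estimated per gene (61587 genes) and per transcript (244998 transcripts), as decimals and not scaled between libraries. The same deposited tables hold TPM values that the authors scaled by length over all genes or transcripts, so that each library sums to 1000000. Each gene's expected counts equalled the sum over its transcripts within 0.05 counts. Gene identifiers were paired with symbols by the name table provided with the annotation, which held 61415 of the 61587, and 123 symbols were shared by several genes. Groups were taken from the treatment given per the labels: the TSC culture with Y27632 at 5 µM; ST, 6 days with forskolin at 2 µM and Y27632 at 2.5 µM; EVT, 6 days and 2 further days after passage, with NRG1 at 100 ng/mL, A83-01 at 7.5 µM and Y27632 at 2.5 µM.

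Rounded expected counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter by group (18040 genes kept) and quasi-likelihood tests. All 6 libraries were fitted together with 3 residual degrees of freedom, which assumes that the groups share a spread. The comparisons were ST against TSC, EVT against TSC and ST against EVT, each two-sided, with Benjamini-Hochberg adjustment over the genes of a comparison and a call at an adjusted p below 0.05. The SE of a log2 fold change is its size over the square root of the F statistic. For a gene without a count in a group, the fold is a lower bound computed with 3 counts over that group; for a group with 1 to 3 counts, the ratio has an exact binomial 95% interval. TMM factors ran from 0.928 to 1.07 and the common biological coefficient of variation was 0.408.

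A set of 34 gene lists (placental and embryonic cell types, other cell types, cell cycle, signalling, metabolism and stress) was fixed before the data were examined, as were the tests, comparisons, threshold, a first set of other settings and the rule for named genes. Lists with at least 5 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with the directional fry test. "Adjusted over the list alone" means the edgeR p-values of a list's members adjusted among themselves. Named genes were a fixed panel of lineage markers; the 8 largest increases and 8 largest decreases among called genes with a symbol, at least 10 TPM in the higher group and no overlap between the libraries of the groups; up to 4 members per described list with the largest called changes; and every called member of a list with 3 or fewer. XIST and Y-linked genes were left out. Genes named outside this rule are marked in the text as chosen after their values were seen.

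Principal components used log2(TPM + 1) of the 2000 most variable genes, centred and scaled. The other settings fixed in advance were DESeq2 size factors in edgeR, library totals, the DESeq2 1.42.0 Wald test, limma on log2(TPM + 1) with pseudocounts of 1, 0.1 and 5, no filter, at least 50 counts in 2 libraries, fits of only the groups compared, the replicate number as a block, other numbers of genes for the components and each library left out in turn. Added after the data were seen were a correction that takes out each library's smooth trend of log2 CPM on log2 transcript length (a spline with 5 degrees of freedom), the same with GC content, and a fit without ST replicate 2 and EVT replicate 1; 4 marker lists for other cell types were also added then. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

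The procedure was tested on simulated data with the same depths and spread. Of 100 genes changed by a log2 of 2, 62% were called, and of 100 changed by 3, 86%, with 12 false calls among 160 and 0 in an unchanged comparison. In camera, a list shifted 2-fold had an adjusted p of 5.76e-27 and 0 of 33 other lists were called. The simulated counts were drawn separately for each gene, so this does not test camera on lists whose members vary together. In the data the estimated correlation reached 0.959 for ribosomal protein genes. The libraries of each group were checked against each other by a chi-square of their counts over genes, and none of these 3 pairs was a duplicate.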

Results

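Poly(A) RNA was sequenced from 6 libraries of a trophoblast culture that had been grown from blastoids, embryo-like structures made from the human embryonic stem cell line KhES1. The libraries formed 3 groups of 2: the stem cell culture (TSC); the same culture after 6 days in a syncytiotrophoblast medium with forskolin, which raises cAMP (ST); and the culture after 6 days in an extravillous trophoblast medium with NRG1 and the TGF-beta receptor inhibitor A83-01, then passage and 2 more days (EVT). Total expected counts were 21023583 and 39072284 in TSC, 25899252 and 31206078 in ST, and 18955177 and 25430462 in EVT. A gene with a count of 0 could hold up to 3 counts by chance, which is between 0.077 and 0.158 CPM in a library. Such floors cover counting error only. The labels do not say whether the libraries of a group came from separate cultures, so every p-value here measures only the spread between these samples, which may be technical. Values per group are a mean ± SD with n = 2, in TPM, the authors' length-scaled unit, unless another unit is given.

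All 6 libraries were rich in transcripts of matrix genes, at levels far above those of most trophoblast markers. COL3A1, a fibrillar collagen, stood at 39042 ± 465 in TSC, 15309 ± 8915 in ST and 18847 ± 13542 in EVT, and the matrix proteoglycan gene DCN at 6932 ± 822, 10089 ± 271 and 10397 ± 1078. COL3A1, DCN, LUM and SPARC were among the 15 most abundant genes in each of the 6 libraries. The simple-epithelium keratins KRT8 and KRT18, which trophoblast expresses too, reached 3212 ± 21.7 and 3315 ± 191 in TSC. They stood at 3737 ± 81.2 and 4062 ± 192 in ST, and at 1965 ± 238 and 2074 ± 9.96 in EVT. These abundant genes were chosen after their values were seen. Of the lists fixed before the data were examined, the mesenchyme list had a median member level of 428 TPM over all libraries, with 15 of 16 members at 10 TPM or more. The same median was 10.9 TPM for pan-trophoblast genes (7 of 14 members at 10 TPM or more), 15.4 TPM for trophoblast stem cell and cytotrophoblast genes (13 of 22) and 8.25 TPM for extravillous trophoblast genes (20 of 41). It was 1.49 TPM for syncytiotrophoblast genes (12 of 49) and 0.331 TPM for primed pluripotency genes (3 of 20). Amnion genes had a median of 25.1 TPM (8 of 16), above each of these trophoblast lists.

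Among single lineage markers fixed before the data were examined, the stem cell regulator TP63 was at 0.287 ± 0.195 TPM in TSC and had no count in ST or EVT. At 3 counts over a group, TP63 was at least 4.73-fold lower in ST and at least 3.68-fold lower in EVT, without a test because its counts were too low. ELF5, another stem cell regulator, had 9 counts in TSC replicate 1 (0.405 TPM) and no count in any other library. The trophectoderm transcription factors CDX2 and TEAD4 stood at 16.6 and 19 TPM in TSC, 14.8 and 19.7 TPM in ST, and 15.4 and 16 TPM in EVT. GATA3 was at 8.26, 2.23 and 2.31 TPM in the 3 groups and TFAP2C at 1.25, 0.397 and 0.193 TPM (0.022 and 0.363 TPM in the EVT libraries). HLA-G, the class I gene typical of extravillous trophoblast, was at 4.46 ± 2.64, 6.09 ± 1.13 and 6.32 ± 3.53 TPM, and its near-identical relatives make these values uncertain. The fusogen genes ERVW-1 and ERVFRD-1 were at 3.64 ± 3.00 and 2.90 ± 1.28 TPM in TSC and 1.93 ± 0.861 and 1.26 ± 0.506 TPM in ST, and did not pass the edgeR test (adjusted p = 0.361 and 0.546). ERVW-1 was at 5.76 TPM in TSC replicate 1 and 1.52 TPM in TSC replicate 2. GCM1, which drives their transcription, did not exceed 0.246 TPM in any library. The pluripotency genes NANOG and SOX2 had no count in any library, and POU5F1 was at 0.085 TPM in TSC.

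**Figure D1:**
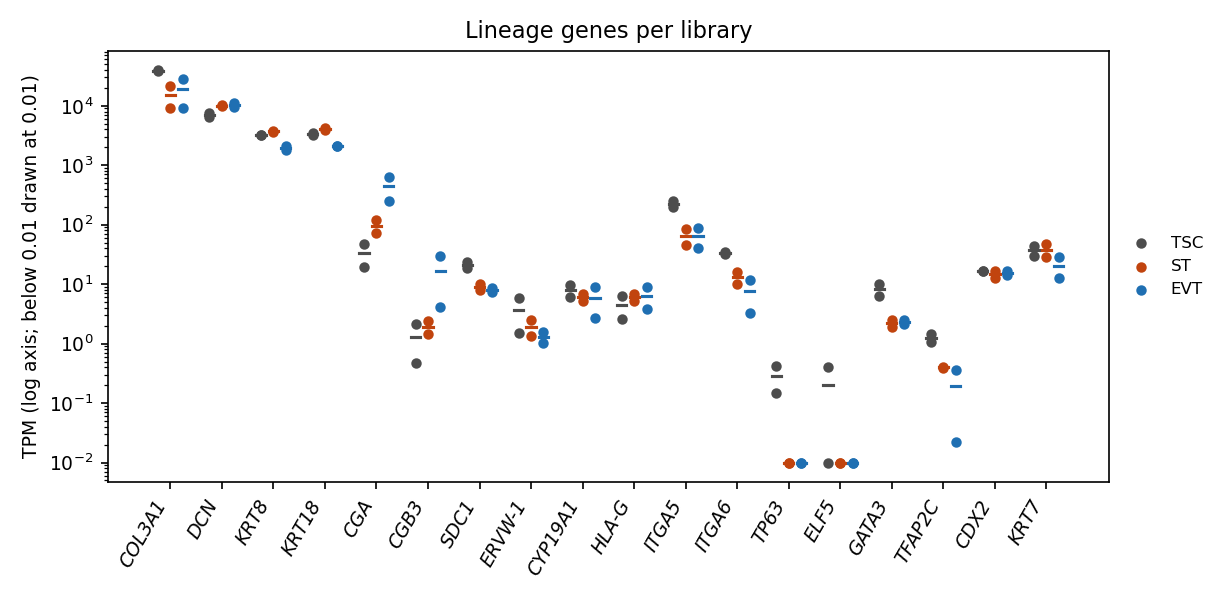
Levels of 18 lineage genes in TPM (log axis) in each library, with points for libraries and bars for group means, grey for TSC, orange for ST and blue for EVT; values below 0.01 TPM are drawn at 0.01. COL3A1 and DCN lie far above the trophoblast markers in all 6 libraries, and CGA is highest in EVT, at 444 TPM.

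The comparison of ST with TSC asks what forskolin medium did to the stem cell culture. In ST, UPK3B, a urothelial and mesothelial surface protein gene, rose from 2.59 ± 0.998 to 186 ± 6.56 TPM (log2 fold change 6.93, SE 0.40, adjusted p = 0.00127). The retinoic acid synthesis gene ALDH1A3 rose from 5.47 ± 0.637 to 284 ± 119 TPM and the cornified envelope gene SPRR2F from 0.663 ± 0.332 to 69.6 ± 8.75 TPM. The dipeptidase gene DPEP1 and the lectin genes ITLN1 and ITLN2 had no count in TSC and reached 16.3 ± 0.753, 22.8 ± 1.82 and 21.6 ± 4.79 TPM. Among the genes that fell, the cadherin-family gene PCDH8 dropped from 113 ± 11.3 to 3.11 ± 2.16 TPM, the cell adhesion gene NFASC from 39.5 ± 8.73 to 1.62 ± 0.378 TPM and the collagen gene COL6A3 from 365 ± 28.0 to 31.4 ± 10.2 TPM.

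Of 18040 genes tested with edgeR, 761 differed between ST and TSC after Benjamini-Hochberg adjustment, 462 higher and 299 lower in ST. The log2 fold changes were 6.16 for ALDH1A3 (SE 0.44), 7.02 for SPRR2F (SE 0.52), 6.88 for the prostaglandin D synthase gene PTGDS (SE 1.00), -5.13 for PCDH8 (SE 1.13), -4.81 for NFASC (SE 0.39) and -4.12 for COL6A3 (SE 0.35). Against 3 counts over the TSC group, DPEP1 was at least 334-fold higher, ITLN1 at least 328-fold and ITLN2 at least 193-fold, although ITLN1 and ITLN2 are close relatives that can share reads. The carboxypeptidase gene CPB1 had 1 count in TSC and 604 in ST, a depth-scaled ratio of 636 with a 95% counting interval from 114 to 25147. Further large decreases were DPYSL5 (-5.99), RTBDN (-5.46), JAKMIP2 (-5.41), COL2A1 (-4.84), CRMP1 (-4.81) and NDNF (-4.77), with adjusted p from 0.0061 to 0.0261 in edgeR. UPK3B lies on chromosome 7 at 76510525 to 76516522, ALDH1A3 on chromosome 15 at 100877714 to 100916626 and COL6A3 on chromosome 2 at 237324003 to 237414328 (GRCh38). Genes higher in ST had a median transcript length of 1518 nt, those lower 3351 nt, and all tested genes 2133 nt.

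No trophoblast list passed the group test in ST. Of 31 measured syncytiotrophoblast genes, 0 rose, 2 fell and 29 did not pass the test (1 higher and 2 lower adjusted over the list alone; edgeR, where 4696 of all 18040 genes had an unadjusted p under 0.05 and DESeq2 called 3002). The members that fell were the growth factor genes GDF15 (log2 -1.37, SE 0.30) and PGF (-1.31, SE 0.26). CGA, the common alpha subunit of the glycoprotein hormones, was at 33.1 ± 19.7 TPM in TSC and 95.9 ± 31.1 TPM in ST (log2 1.98, SE 0.67, adjusted p = 0.12). The chorionic gonadotropin beta genes CGB3 and CGB5, near-identical copies whose reads can be assigned to either, were at 1.31 and 1.01 TPM in TSC and 1.92 and 1.17 TPM in ST. SDC1, a syncytiotrophoblast surface marker, was at 21.1 TPM in TSC and 9.02 TPM in ST (log2 -1.0, adjusted p = 0.0937). The camera test gave the syncytiotrophoblast list an adjusted p of 0.415, the pan-trophoblast list 0.564, the extravillous list 0.188 and the cell fusion list 0.434. In the extravillous list of 33 measured genes, the protease gene HTRA1 (log2 2.40) and FSTL3 (1.53) rose and MCAM (-1.92) fell, and 3 were higher and 9 lower adjusted over the list alone. Of 19 stem cell and cytotrophoblast genes, 1 rose, the differentiation inhibitor ID2 (log2 1.34), and the list did not pass the camera test (adjusted p = 0.0659, median log2 -0.44; 0.0408 without both ST replicate 2 and EVT replicate 1, and 0.756 on all libraries with an estimated correlation). Of 16 measured cAMP and CREB target genes 1 rose and 0 fell (2 higher and 1 lower adjusted over the list alone). That list was not called (camera adjusted p = 0.492). Its median log2 was 0.22, and -0.16 on log2(TPM + 1) values.

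Antigen presentation, histone, ribosomal protein and respiratory chain genes were higher in ST as groups in camera, each with an adjusted p = 0.756 with an estimated correlation. In the HLA class I and antigen presentation list 3 of 13 measured genes rose and 0 fell (6 higher adjusted over the list alone): the immunoproteasome genes PSMB8 (from 16.6 ± 3.48 to 121 ± 21.2 TPM, log2 3.22) and PSMB9 (log2 3.20) and B2M (2.15). Its camera adjusted p was 0.000216, and adjusted p = 0.756 with an estimated correlation. Of 11 replication-dependent histone genes 5 rose and 0 fell (6 higher adjusted over the list alone), among them H2AC6, from 7.78 ± 2.39 to 69.9 ± 3.45 TPM, and H2BC4, from 2.17 ± 1.47 to 20.5 ± 4.40 TPM. These genes have near-identical copies and mostly lack a poly(A) tail, and the list had a camera adjusted p of 0.000119 and an adjusted p = 0.756 with an estimated correlation. Of 40 ribosomal protein genes 2 rose, RPS18 (log2 2.63) and RPS3A (2.01), and 0 fell, with 23 higher adjusted over the list alone, a median log2 of 1.12 and a camera adjusted p of 2.46e-10 (adjusted p = 0.756 with an estimated correlation). Their pseudogenes make single values uncertain. Of 28 oxidative phosphorylation genes 1 rose, SDHD (log2 1.52), and 0 fell, with 2 higher adjusted over the list alone (median 0.90, camera adjusted p = 0.000216; adjusted p = 0.756 with an estimated correlation). These 3 lists hold short transcripts (median 787, 735 and 1043 nt), and with each library's trend on transcript length taken out, a setting added after the data were seen, their medians were 1.24, 0.23 and 0.03 and their camera adjusted p-values 0.0731, 0.0216 and 0.669. Only the ribosomal list was still called, with an adjusted p = 0.836 with an estimated correlation. The interferon response list was higher without a single gene passing (0 of 20 over all genes, 5 higher adjusted over the list alone, median 0.75, camera adjusted p = 0.0378; adjusted p = 0.756 with an estimated correlation), and without ST replicate 1 its adjusted p was 0.0731. With the length trend taken out, the interferon median was 0.14 and the adjusted p 0.141.

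Primed pluripotency, neural, epithelial-mesenchymal transition and transporter lists were lower in ST than in TSC in camera, each with an adjusted p = 0.756 with an estimated correlation. Of 11 primed pluripotency genes 3 fell and 0 rose (4 lower adjusted over the list alone, median -2.05): DPPA4, from 24.3 ± 6.54 to 4.2 ± 1.67 TPM, SALL4, from 1.21 ± 0.0905 to 0.054 ± 0.0438 TPM, and LIN28A, at 1.46 TPM in TSC with no count in ST. The nutrient transporter list had 2 genes that fell, the glucose transporter gene SLC2A3 (log2 -2.62) and the cystine transporter gene SLC7A11 (-2.34), and 1 that rose, the cationic amino acid exchanger gene SLC7A7 (2.00), of 21 measured (3 higher and 8 lower adjusted over the list alone, median -0.59). Of 16 epithelial-mesenchymal transition genes 1 fell, the matrix glycoprotein gene TNC (log2 -2.76), and 0 rose (1 higher and 4 lower adjusted over the list alone, median -0.48). Of 5 neural and ectoderm genes 0 passed over all genes and 3 were lower adjusted over the list alone (median -1.90). Camera adjusted p-values were 0.0394 for the pluripotency, transporter and neural lists and 0.0416 for the transition list. Leaving out a library raised the adjusted p of the pluripotency list to 0.0551 (TSC replicate 2), 0.0583 (ST replicate 1) and 0.0539 (ST replicate 2), of the transporter list to 0.0645, 0.0511 and 0.0652 without the same libraries. The neural list was at 0.0559 without TSC replicate 1 and 0.157 without ST replicate 1. The transition list was at 0.163 without TSC replicate 2 and 0.0928 without ST replicate 2. With the length trend taken out, the values were 0.098 for the pluripotency list (median -1.96) and 0.0667 for the transition list (median -0.26). Without both ST replicate 2 and EVT replicate 1 they were 0.146 and 0.107. On log2(TPM + 1) values the pluripotency list was at 0.112 (median -1.09) and the transporter list at 0.109.

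The number of genes called between ST and TSC moved widely with single libraries: it was 58 without TSC replicate 1, 28 without TSC replicate 2, 382 without ST replicate 1 and 68 without ST replicate 2. It was 3497 without EVT replicate 1 and 3429 without EVT replicate 2, since EVT shares the estimate of spread, and 2661 without both ST replicate 2 and EVT replicate 1, where the spread comes from the TSC pair alone. On log2(TPM + 1) values the median of all genes was -0.22 for ST against TSC and -0.37 for EVT against TSC, and limma called 373 genes higher and 390 lower in ST.

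**Figure D2:**
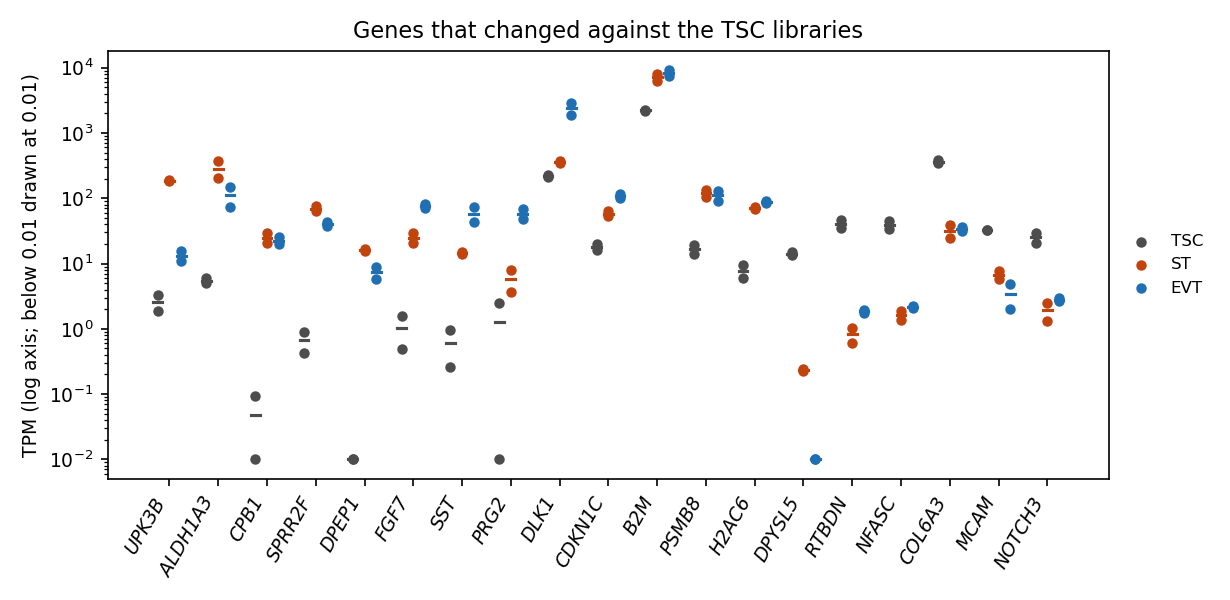
Levels of 19 genes that changed against TSC, in TPM (log axis) in each library, with points for libraries and bars for group means, grey for TSC, orange for ST and blue for EVT; values below 0.01 TPM are drawn at 0.01. UPK3B stands at 186 TPM in ST and 13.1 TPM in EVT, DLK1 at 363 and 2382 TPM.

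The comparison of EVT with TSC asks what the extravillous medium did to the same culture. In EVT, the growth factor gene FGF7 rose from 1.04 ± 0.776 to 76.4 ± 6.63 TPM (log2 7.35, SE 0.40, adjusted p = 0.00164) and DLK1, an imprinted NOTCH-family ligand gene, from 217 ± 9.72 to 2382 ± 745 TPM (log2 3.90, SE 0.28, adjusted p = 0.00288). The hormone gene CGA rose from 33.1 ± 19.7 to 444 ± 274 TPM (log2 4.36, SE 0.74, adjusted p = 0.0203), and PRG2, a decidual and extravillous secreted protein gene, from 1.25 ± 1.77 to 58.2 ± 15.2 TPM (log2 5.91, SE 1.16, adjusted p = 0.028). The integrin gene ITGA6, a cytotrophoblast marker, dropped from 33.3 ± 2.26 to 7.53 ± 6.09 TPM (log2 -1.94, SE 0.40, adjusted p = 0.0318). Genes of DNA replication and of G2/M were lower as groups in camera, with an adjusted p = 0.581 and an adjusted p = 0.496 with an estimated correlation. DPYSL5, a neuronal gene, went from 14.2 ± 1.26 TPM to no count.

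Over all 18040 genes edgeR called 1572 in EVT against TSC, 904 higher and 668 lower. Other large increases were SST (log2 7.01), PTGDS (6.42), SPRR2F (6.35), FBXO32 (5.86) and UBA7 (5.71), and CPB1 went from 1 count to 451, a depth-scaled ratio of 611 with a 95% counting interval from 109 to 24171. Against 3 counts over the EVT group, DPYSL5 was at least 519-fold lower. ATCAY had 1043 counts in TSC and 2 in EVT, a depth-scaled ratio of 385 with a 95% counting interval from 106 to 3185. Further decreases were JPH4 (-6.06), TUBB4A (-5.61) and CRMP1 (-5.08), with edgeR adjusted p from 0.00862 to 0.0178. KALRN, the NOTCH ligand gene JAG1 and FSD1 also fell, from 15.8, 10.3 and 15.6 TPM in TSC, with no count in EVT replicate 1 and 12, 39 and 19 counts in EVT replicate 2. Their adjusted p-values were 0.0223, 0.037 and 0.0398, and they passed in 16, 15 and 14 of 19 other settings. The sign held in all 19, but the fitted log2 of JAG1 ran from -12.72 to -1.53. DLK1 lies on chromosome 14 at 100725705 to 100738224, CGA on chromosome 6 at 87085498 to 87095106 and FGF7 on chromosome 15 at 49423237 to 49488775. The median transcript length was 1399 nt for genes higher in EVT and 3573 nt for genes lower.

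Of 33 measured extravillous genes 5 rose and 2 fell (6 higher and 9 lower adjusted over the list alone), with PRG2, SERPINE2 (log2 2.2) and HTRA1 (1.80) higher and MCAM lower (-3.16), and the list did not pass the camera test (adjusted p = 0.434). HLA-G was at 6.32 TPM in EVT and 4.46 TPM in TSC (adjusted p = 0.37). ITGA5 and ITGA1, integrins of the invasive phenotype, were at 63.8 and 28.7 TPM in EVT against 222 and 106 TPM in TSC. Neither integrin gene passed the edgeR test (adjusted p = 0.0584 and 0.0958). Of 31 syncytiotrophoblast genes 3 rose, CGA, the inhibin gene INHA (log2 3.42) and the protease inhibitor gene TFPI2 (2.23), and 1 fell, GDF15 (-1.23), with 10 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.102). That list was called higher without TSC replicate 1 (0.0398) or EVT replicate 2 (0.0422), and on all libraries its adjusted p with an estimated correlation was 0.675. CGB3 was at 16.8 ± 18.1 TPM in EVT (log2 4.36, adjusted p = 0.0577) and CGB5 at 9.80 ± 11.4 TPM. Of 19 stem cell and cytotrophoblast genes 4 fell, TCF7 (log2 -4.18), ITGA2 (-2.87), ID1 (-2.18) and ITGA6, and 0 rose (8 lower adjusted over the list alone, median -0.75). That list's camera adjusted p was 0.0195, with an adjusted p = 0.496 with an estimated correlation, and it was 0.066 without EVT replicate 2. With the length trend taken out, its median was -0.30 and its adjusted p 0.081, and ITGA2 did not pass (log2 -1.90, adjusted p = 0.0781). Among imprinted genes expressed in placenta, 3 of 17 rose, DLK1, the cell cycle inhibitor gene CDKN1C (from 18.0 ± 2.48 to 108 ± 12.1 TPM) and SGCE (log2 1.73), and 0 fell (5 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.0561). The imprinted list was called higher with fry (0.0396), on log2(TPM + 1) values (0.0257) and with the length trend taken out (0.0243), but not with an estimated correlation, without (0.496) or with the length correction (0.493).

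Of 24 DNA replication genes 5 fell and 0 rose (11 lower adjusted over the list alone, median -0.84), among them the helicase gene MCM2, from 51.3 ± 15.1 to 10.5 ± 3.52 TPM, GINS1, from 17.3 ± 4.04 to 2.80 ± 1.70 TPM, and POLA1, from 18.7 ± 1.67 to 4.97 ± 0.890 TPM. Of 24 G2/M genes 3 fell and 0 rose (8 lower adjusted over the list alone, median -0.55): the proliferation marker MKI67, from 25.6 ± 3.13 to 7.70 ± 1.99 TPM, KIF11 (log2 -1.53) and TPX2 (-1.14). Camera gave adjusted p-values of 0.00206 and 0.00691, with an adjusted p = 0.581 with an estimated correlation for the replication list and an adjusted p = 0.496 with an estimated correlation for G2/M. The G2/M value was 0.0812 without EVT replicate 2. With the length trend taken out both lists were still called (medians -0.64 and -0.34, adjusted p = 0.00083 and 0.00275), though not with an estimated correlation (adjusted p = 0.493 and 0.551). Under that setting MKI67 (log2 -0.25, adjusted p = 0.611), KIF11 (-0.58, 0.163), TPX2 (-0.48, 0.144) and POLA1 (-0.90, 0.085) did not pass. WNT, NOTCH and transporter lists were also lower: of 13 WNT target genes 2 fell, TCF7 and ZNRF3 (log2 -1.71), and 0 rose (3 lower adjusted over the list alone, median -0.95, camera adjusted p = 0.0285; adjusted p = 0.496 with an estimated correlation). Of 11 NOTCH pathway genes 3 fell, JAG1, NOTCH3 (-3.12) and HEY1 (-2.77), and 0 rose (3 lower adjusted over the list alone, median -0.98, camera adjusted p = 0.0371; adjusted p = 0.496 with an estimated correlation). The NOTCH value was 0.0592 without TSC replicate 1, 0.0658 without EVT replicate 2 and 0.062 with the length trend taken out (median -0.21), a setting under which ZNRF3 did not pass (log2 -0.84, adjusted p = 0.14). Of 21 nutrient transporter genes 3 fell, SLC7A8 (-2.61), SLC7A5 (-2.18) and SLC2A3 (-2.16), and 1 rose, the lactate transporter gene SLC16A3 (1.43), with 3 higher and 7 lower adjusted over the list alone. The transporter median was -0.93, or -0.58 with a member that had no count in a group set at its bound, and the camera adjusted p was 0.0225 (adjusted p = 0.631 with an estimated correlation). The transporter median was -0.46 with the length trend taken out, at an adjusted p of 0.0235 (0.551 with an estimated correlation).

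Of 40 ribosomal protein genes 8 rose and 0 fell (35 higher adjusted over the list alone), RPS18 by a log2 of 2.90 and RPS7 by 1.93, with a median of 1.28 and a camera adjusted p of 1.46e-11 (adjusted p = 0.581 with an estimated correlation). Of 28 oxidative phosphorylation genes 4 rose, NDUFA4 (2.2), COX7A2 (2.13), NDUFA1 (2.05) and SDHD (1.60), and 0 fell (17 higher and 1 lower adjusted over the list alone, median 0.99, camera adjusted p = 0.000183; adjusted p = 0.581 with an estimated correlation). Of 11 histone genes 5 rose and 0 fell (7 higher adjusted over the list alone), H2AC6 to 86.9 ± 4.63 TPM and H2BC5 from 4.89 ± 0.0686 to 27.7 ± 7.16 TPM (median 2.53, camera adjusted p = 0.000521; adjusted p = 0.581 with an estimated correlation). With the trend on transcript length taken out, these 3 medians were 0.43, 0.18 and 1.48 and the adjusted p-values 0.000215, 0.158 and 0.087. Only the ribosomal list was still called, with an adjusted p = 0.678 with an estimated correlation. In the antigen presentation list 4 of 13 genes rose, PSMB8 (3.23), PSMB9 (3.03), B2M (2.48) and HLA-E (1.00), and 0 fell (7 higher adjusted over the list alone, median 0.93, camera adjusted p = 0.00104; adjusted p = 0.496 with an estimated correlation).

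Interferon response genes were higher in EVT, with 3 of 20 rising and 0 falling (12 higher adjusted over the list alone): IRF7 (log2 4.61), IFIT3 (2.94) and IFIT1 (2.38). The list's median was 1.90 and its camera adjusted p 0.00127 (adjusted p = 0.581 with an estimated correlation), and the adjusted p was 0.119 without EVT replicate 1. That library stood apart within its group: ISG15 was at 532 TPM in EVT replicate 1 and 52.3 TPM in EVT replicate 2, and IFI6 at 983 and 73.6 TPM. In TSC, ISG15 was at 50.2 and 60.1 TPM and IFI6 at 106 and 96.2 TPM. The mitochondrial chromosome held 3.65% of the counts in EVT replicate 1 and 1.28% in EVT replicate 2. ISG15 and IFI6 were chosen after their values were seen.

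The count of 1572 genes between EVT and TSC was 51 without TSC replicate 1, 66 without TSC replicate 2, 5932 without EVT replicate 2 and 3571 without both ST replicate 2 and EVT replicate 1. This last setting takes the spread from the TSC pair alone. On log2(TPM + 1) values limma called 622 genes higher and 1352 lower.

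The comparison of ST with EVT asks how far the differentiation media gave different products. Only UPK3B and DLK1 passed the gene test: UPK3B was at 186 ± 6.56 TPM in ST and 13.1 ± 3.34 TPM in EVT (log2 3.57, SE 0.33, adjusted p = 0.0477), and DLK1 at 363 ± 20.8 and 2382 ± 745 TPM (log2 -2.87, SE 0.27, adjusted p = 0.0477). Both genes had libraries that did not overlap between the groups. HLA-G, CGA, SDC1 and the other fixed lineage markers did not pass, with CGA at 95.9 ± 31.1 TPM in ST and 444 ± 274 TPM in EVT. Syncytiotrophoblast genes as a group were lower in ST than in EVT in camera and replication genes higher, each with an adjusted p = 0.351 with an estimated correlation.

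Of 31 measured syncytiotrophoblast genes, 27 had a lower and 4 a higher fitted value in ST than in EVT, 0 passed over all genes (edgeR, 910 of all genes with an unadjusted p under 0.05; DESeq2 called 149 genes) and 5 were lower adjusted over the list alone. The list's median was -0.85 and its camera adjusted p 1.56e-08 (adjusted p = 0.351 with an estimated correlation). EVT replicate 1 stood apart on this list, with a median member level of 2.18 TPM against 0.741 TPM in EVT replicate 2 and 0.619 and 0.884 TPM in ST, and with CGB3 at 29.6 TPM against 4.06 TPM in EVT replicate 2. Without EVT replicate 1 the list's camera adjusted p was 0.00151. Unfolded protein response genes were lower in ST in 17 of 18 members, with 0 passing over all genes or over the list alone (median -0.62, camera adjusted p = 1.96e-09; adjusted p = 0.351 with an estimated correlation). Of 17 placental imprinted genes 14 were lower, 1 of them, DLK1, past the test (3 lower adjusted over the list alone, median -0.45, camera adjusted p = 1.16e-05; adjusted p = 0.257 with an estimated correlation). Of 24 DNA replication genes 23 were higher in ST and 0 passed, with 2 adjusted over the list alone (median 0.49, camera adjusted p = 2.75e-07; adjusted p = 0.351 with an estimated correlation). All 24 G2/M genes were higher in ST and 0 passed (median 0.37, camera adjusted p = 3.24e-05; adjusted p = 0.257 with an estimated correlation), and the adjusted p was 0.0713 without EVT replicate 2. All 13 mitochondrially encoded genes were lower in ST and 0 passed (median -1.01, camera adjusted p = 2.96e-07; adjusted p = 0.619 with an estimated correlation). Without EVT replicate 1, the library with the high mitochondrial share, the camera adjusted p was 0.852.

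A further 9 lists were called by camera between ST and EVT, none with a gene past the edgeR test over all genes. Steroid hormone synthesis (median -0.40, adjusted p = 0.00308), epithelial-mesenchymal transition (-0.24, 0.0054) and cAMP target genes (-0.27, 0.0249) were lower in ST. Cholesterol synthesis (0.23, 0.0249), NOTCH pathway (0.79, 0.0249), TGF-beta target (0.29, 0.0288; 3 higher and 1 lower adjusted over the list alone) and stem cell and cytotrophoblast genes (0.23, 0.0319) were higher. Each of these 7 lists lost its call without at least 1 library. The steroid list lost it without ST replicate 1 (0.102) or EVT replicate 1 (0.0834), the transition list without ST replicate 2 (0.432) or EVT replicate 2 (0.511) and the cholesterol list without ST replicate 2 (0.0567) or EVT replicate 1 (0.385). The cAMP list lost it without ST replicate 1 (0.0926), EVT replicate 1 (0.128) or EVT replicate 2 (0.083). The NOTCH list lost it without ST replicate 2 (0.121), EVT replicate 1 (0.0834) or EVT replicate 2 (0.0674). The TGF-beta list lost it without ST replicate 1 (0.0926), EVT replicate 1 (0.0834) or EVT replicate 2 (0.156). The stem cell list lost it without ST replicate 1 (0.15), ST replicate 2 (0.0535), EVT replicate 1 (0.0743) or EVT replicate 2 (0.156), and with the length trend taken out (median 0.02, adjusted p = 0.0603). Interferon response genes were lower in ST (median -0.61, adjusted p = 0.0249), with values of 0.0926 without ST replicate 1 and 0.0748 without ST replicate 2, and were higher in ST without EVT replicate 1 (0.00282). Ribosomal protein genes were lower in ST (median -0.18, adjusted p = 0.0264), and higher in ST without ST replicate 1 (0.0132) or EVT replicate 1 (3.9e-05). On log2(TPM + 1) values the stem cell (0.0806), cAMP (0.223), NOTCH (0.253) and ribosomal protein lists (0.0668) were not called. With an estimated correlation the adjusted p of these 9 lists ran from 0.351 to 0.943.

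The calls between ST and EVT rested on most of the libraries: edgeR called 0 genes without TSC replicate 1, TSC replicate 2, ST replicate 1 or ST replicate 2 (698, 702, 459 and 763 genes with an unadjusted p under 0.05), 6 without EVT replicate 1 and 468 without EVT replicate 2. With both ST replicate 2 and EVT replicate 1 left out, each of these groups has a single library and the spread comes from the TSC pair alone, with 1 degree of freedom. It called 47 genes. DESeq2 on all libraries called 149.

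ST and EVT changed in common against TSC. Of the genes called in either comparison, 618 were called in both in the same direction, 396 higher, such as CPB1, PTGDS, SPRR2F and the antigen presentation genes PSMB8 and B2M, and 222 lower, such as DPYSL5, CRMP1, COL6A3 and NOTCH3, and 0 in opposite directions (edgeR; DESeq2 shared 2401 with 1 in opposite directions). Independent lists of these sizes would share 23.2 higher and 11.1 lower genes. In 20 simulated sets of unchanged groups that shared their controls, the highest number of shared calls was 0. Those sets held no changed genes, so they cannot show how far shared controls raise the overlap where genes do change. Both comparisons use the same 2 TSC libraries, which were not split between them here, so part of the excess may come from the shared controls. Both also ran with transcript length, at a Spearman correlation across genes of -0.487 for ST minus TSC and -0.481 for EVT minus TSC. With the length trend taken out, 689 of the 761 ST calls and 1308 of the 1572 EVT calls were still called in the same direction. How many of the shared calls follow that trend was not tested. HTRA1, RSPO3 and HSD17B2 were among the list members higher in both, with RSPO3, a WNT-enhancing secreted protein gene, at 4.07 ± 2.91 TPM in TSC, 28.6 ± 2.83 TPM in ST and 37.1 ± 4.01 TPM in EVT.

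The TSC libraries lay apart from the differentiated libraries, while the position of ST and EVT libraries within their groups depended on the genes used. On principal components of the 2000 most variable genes, the first component held 69.0% of the variance, with TSC at -42.9 and -44.7, ST at 5.1 and 26.9 and EVT at 47.4 and 8.3. On the plane of the first components the EVT libraries were 48.5 apart and ST replicate 1 and EVT replicate 2 16.2 apart, but with the 500 most variable genes these distances were 13.6 and 18.9. Pearson's r of log2(TPM + 1) across genes, which are not independent replicates, was 0.969 within TSC, 0.967 within ST and 0.931 within EVT. It was 0.963 between ST replicate 1 and EVT replicate 2 and 0.957 between ST replicate 2 and either EVT library, all above the value within EVT. Between ST replicate 1 and EVT replicate 1 it was 0.925. The libraries also differed in the balance of short and long transcripts. The Spearman correlation across genes between transcript length and a gene's deviation from its mean was 0.388 and 0.505 in TSC, 0.067 and -0.528 in ST, and -0.488 and 0.037 in EVT. Genes of the shortest length decile (876 nt or less), beside list medians of 735 nt for ribosomal protein and 787 nt for histone genes, had a median deviation of 0.93 in EVT replicate 1 and -0.19 in EVT replicate 2.

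**Figure D3:**
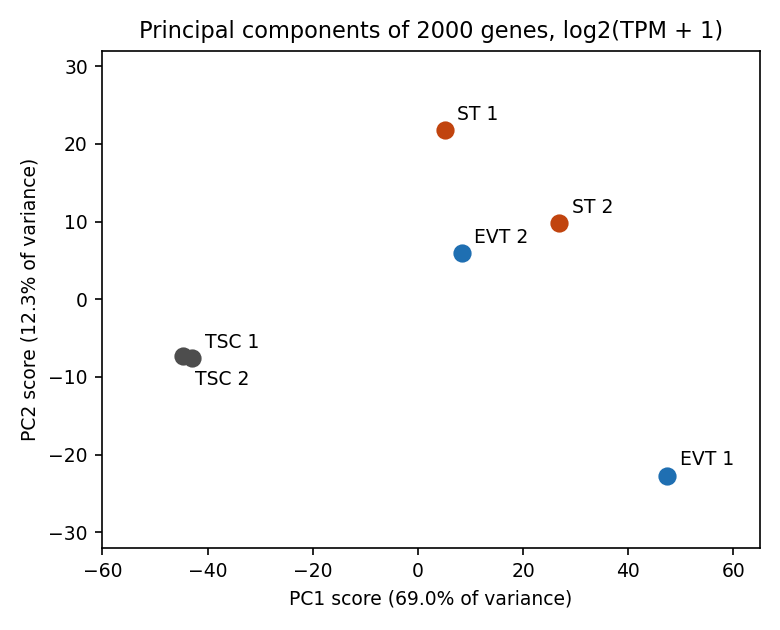
Principal components of log2(TPM + 1) for the 2000 most variable genes, with 1 point per library, grey for TSC, orange for ST and blue for EVT; the axes give scores and their share of the variance, 69.0% and 12.3%. The TSC points nearly coincide, while the EVT points lie farther from each other than ST replicate 1 lies from EVT replicate 2, an order that is reversed with the 500 most variable genes (13.6 and 18.9).

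**Figure D4:**
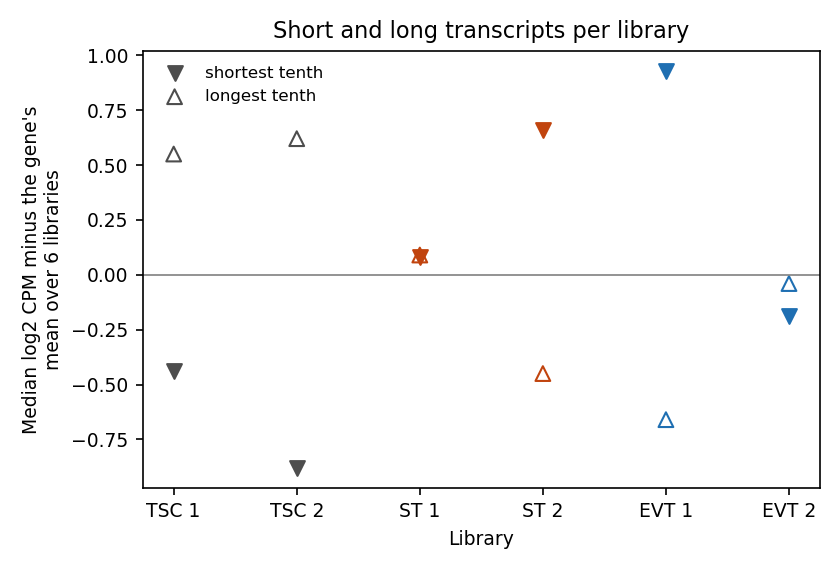
Median log2 CPM minus the gene's mean over the 6 libraries, for the shortest (filled triangles) and the longest (open triangles) length decile of transcripts, per library, grey for TSC, orange for ST and blue for EVT. The shortest decile stands at 0.66 in ST replicate 2 and 0.93 in EVT replicate 1, and at -0.88 in TSC replicate 2.

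Transcript tables gave a view of isoforms in the same libraries, without a test. A transcript of the VEGF receptor gene FLT1 that ends before the gene's last exons (ENST00000541932.5, chromosome 13 at 28368096 to 28495128) took 57.5% and 57.9% of the gene's TPM in TSC, 72.5% and 80.8% in ST and 85.9% and 68.6% in EVT. The gene's total was 173 and 225 TPM in TSC, 89.7 and 49.8 TPM in ST and 67.9 and 126 TPM in EVT. This transcript has 2969 nt, against 6453 and 7123 nt for longer ones. Its share was highest in ST replicate 2 and EVT replicate 1, where short transcripts were high. A 1911 nt transcript of the gene went the other way, at 3.5% and 6.8% in these libraries. Whether the share follows the length trend was not tested. For the matrix gene FN1, the full-length transcript ENST00000354785.11 (8390 nt) took 37.7% and 38.0% in TSC and 30.7% in ST replicate 1, but 0.6% in ST replicate 2 and 0.0% in EVT replicate 1. A 676 nt transcript at its 3' end, ENST00000494446.1, took 37.3% and 42.1% in these last 2 libraries and at most 0.5% in the others. The 3 most abundant transcripts of CYP19A1, the aromatase gene, shared the start at position 51338596 of chromosome 15, and the isoforms of TP63, PAPPA2 and HLA-G were too low to compare. These shares are of estimated TPM rather than of counts, so no binomial interval applies.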

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

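Of the tests in this part, that of reads weighted to the 3' ends of transcripts was set before its result was seen, while those of the length trend as a whole cause and both tests of the interferon genes were chosen only after the results were seen.

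UPK3B and DLK1 stood out because their changes against TSC differed between ST and EVT in a direct edgeR test. The difference between ST and EVT was a log2 of 3.57 for UPK3B and -2.87 for DLK1, each with an adjusted p = 0.0477. For UPK3B 9 and for DLK1 10 of 19 alternatives kept the adjusted p under the threshold, all 19 with the same sign. With the length trend taken out both stayed past the threshold, at a log2 of 3.59 and -2.95, and no other technical explanation was tested for them.

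In ST replicate 2 and EVT replicate 1, short transcripts were high and long ones low against the other library of the group (Spearman correlations of the difference with length of -0.511 and -0.459 across genes), and the short-transcript ribosomal protein and oxidative phosphorylation lists were higher in ST and EVT than in TSC. For reads weighted to 3' ends, a median shift of at least 5 percentage points had been predicted in the share of short-transcript counts at the 3' end of 350 long genes, and it was not seen: the median shift was 0.0 in both groups, under the bound of 1 set beforehand as evidence against this explanation. That bound was judged uninformative only after the result was seen, because 37.1% and 37.4% of the genes stood within 1 point of 0 or 100 in both libraries. The median was also 0.0 in 3 other library pairs. The explanation is left open, with a median share of 44.6% and 43.6% in the trend's libraries and 19.4% to 26.8% in the others. Pooled over the genes the gaps were smaller. The pooled share was 58.1% in ST replicate 2 and 53.0% in ST replicate 1, and 56.8% in EVT replicate 1 and 54.0% in EVT replicate 2. No biological explanation was tested. With the trend taken out, the ribosomal calls held in camera (adjusted p = 0.0216 and 0.000215), but not with an estimated correlation (adjusted p = 0.836 and 0.678). The bound against the trend as their whole cause also asked for a larger median in both comparisons than the 0.23 left in ST. The trend as their whole cause therefore stays open. The ribosomal median went from 1.12 to 0.23 in ST (quartiles 0.80 and 1.50, then 0.03 and 0.58) and from 1.28 to 0.43 in EVT (0.94 and 1.71, then 0.14 and 0.76). The oxidative phosphorylation calls ended as their medians shrank from 0.90 to 0.03 (0.26 and 1.36, then -0.17 and 0.30) and from 0.99 to 0.18 (0.18 and 1.61, then -0.10 and 0.59).

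Interferon response genes were higher in EVT replicate 1 than in EVT replicate 2, by a median log2 of 1.66 over 20 genes, 19 of them higher. The tables argue against the length trend as the cause: with it taken out, the median was 1.3 (quartiles 0.57 and 2.52) and 20 of 20 genes were higher. A state that EVT replicate 1 shares with ST replicate 2 was tested by the same list's difference between the ST libraries, which was 0.35 (21% of 1.66, between the bounds of 20% against and 50% for it), and -0.05 with the trend taken out, under the bound against it. Neither value reaches the bound for it, so the shared state may be no more than a partial source and stays open as that. No biological explanation was tested.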

How the results depend on the processing

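Of the alternatives, the correction for transcript length, that for length and GC content, and the fit without ST replicate 2 and EVT replicate 1 were chosen only after the data were seen; the others were planned. For the counts of changed genes (761 in ST against TSC, 1572 in EVT against TSC, 2 in ST against EVT), DESeq2 gave 3002, 4222 and 149; no filter gave 2875, 3970 and 200; the length correction gave 1546, 2477 and 48, with GC content 1628, 2430 and 46; and leaving out both libraries, which takes the spread from the TSC pair alone, gave 2661, 3571 and 47. A replicate block gave 78, 127 and 0, all of the 78 and 127 among the genes called without it. Whether replicate numbers pair the samples is not settled. Deviations of replicate 1 from 2 correlated across genes at -0.057 (TSC with ST), 0.116 (TSC with EVT) and -0.259 (ST with EVT). The length trend lies in ST replicate 2 but EVT replicate 1, so these values cannot exclude a pairing. In ST against TSC limma gave 397 with a pseudocount of 0.1 and 1150 with 5, and a fit of the compared groups alone 3560; in EVT against TSC a pseudocount of 5 gave 2592. In ST against EVT, DESeq2 size factors, at least 50 counts and the compared groups alone gave 0 in edgeR (923, 753 and 603 genes with an unadjusted p under 0.05; the block 609), and library totals and a pseudocount of 0.1 gave 1. With 1 library left out, which assumes that the lone library varies like the other groups, the counts ran from 28 (without TSC replicate 2) to 3497 (without EVT replicate 1), from 51 (without TSC replicate 1) to 5932 (without EVT replicate 2) and from 0 (without either TSC or either ST library) to 468 (without EVT replicate 2). Shared calls, 618, were 2401 with DESeq2. Of the called gene lists (9, 11 and 15), an estimated correlation in camera kept 0, 0 and 0 (0, 1 and 3 with an unadjusted p under 0.05) and fry called 0, 4 and 0 (7, 14 and 5); leaving out both libraries gave 6 in EVT against TSC (lost: WNT 0.0652, NOTCH 0.0694, histones 0.0712, transporters 0.0521, interferon 0.123) and 7 in ST against EVT, and leaving out 1 library gave 5 to 11, 10 to 13 and 9 to 15. Between ST and EVT, interferon genes changed direction without EVT replicate 1 (0.00282; adjusted p over the leave-one-out fits from 6.46e-10 to 0.0926), and ribosomal protein genes without ST replicate 1 (0.0132) and without EVT replicate 1 (3.9e-05; from 2.08e-10 to 0.0361). Left-out libraries and groups change the number of samples behind the spread, and no filter changes the genes tested; elsewhere the cause was not tested. All 59, 100 and 2 named called genes kept their sign in every alternative, and 9, 12 and 0 stayed past the threshold in all of them. The first principal component held 44.1% to 69.0% of the variance, and the EVT libraries lay farther apart than ST replicate 1 from EVT replicate 2 in each setting but that of 500 genes. Depth limits single genes: with 3 counts the floor was 0.077 to 0.158 CPM.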

Other observations

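The test of mesothelial markers in this part was set before its result was seen, on marker lists that were added after the other data had been seen.

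Members of the amnion and endoderm lists also changed. BMP4, a growth factor gene active in amnion and mesoderm, fell in EVT, from 658 ± 57.1 to 187 ± 4.97 TPM (log2 -1.31, SE 0.26, edgeR adjusted p = 0.029), and stood at 318 ± 27.3 TPM in ST. The BMP-responsive genes ID1 and ID3 fell in EVT, from 70.6 ± 4.48 to 10.9 ± 2.70 TPM and from 77.5 ± 22.3 to 10.1 ± 1.42 TPM. The EVT medium also held the TGF-beta receptor inhibitor A83-01. Of 16 TGF-beta target genes 1 rose and 3 fell in EVT (2 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.379). Which signal lies behind the falls of ID1 and ID3 was not tested. Of 14 measured amnion genes 3 fell in EVT, BMP4, HEY1 and TNC, and 0 rose (3 lower adjusted over the list alone), and the list was not called (camera adjusted p = 0.534). Of 11 hypoblast and endoderm genes 2 rose and 2 fell in ST (2 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.434): APOA1, at least 62.4-fold higher against 3 counts over TSC, and RSPO3 rose, and LAMA1 (log2 -3.47) and PDGFRA (-2.11) fell.

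Steroid and glucose metabolism genes changed singly against TSC. The estradiol-oxidising gene HSD17B2 rose from 38.7 ± 6.72 TPM in TSC to 106 ± 1.18 TPM in ST (log2 1.73) and 172 ± 19 TPM in EVT (2.58), and STAR, which moves cholesterol into mitochondria, rose in EVT from 0.763 ± 0.0919 to 6.77 ± 1.42 TPM. Of 14 measured steroid synthesis genes 3 rose and 1 fell in EVT (4 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.085). The hypoxia target CA9 had no count in TSC and 9.12 ± 0.687 TPM in ST, at least 141-fold higher, while the glycolysis genes SLC2A3, ENO2 (log2 -1.71) and PFKP (-1.08) fell. Of 23 hypoxia and glycolysis genes 1 rose and 3 fell in ST (1 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.171). With the length trend taken out that list was called lower in ST (0.0226) and EVT (0.0189), and in EVT also on log2(TPM + 1) values (0.0203). With an estimated correlation it was not called, at 0.756 and 0.731, or 0.836 and 0.571 with the length trend taken out.

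Mesenchymal transcripts were abundant and most trophoblast markers far lower in every library, with COL3A1 at 39042 ± 465 TPM and LUM at 11691 ± 663 TPM in TSC. A candidate source is mesothelium-like cells: of 19 mesothelial markers whose values had not been seen, 42.1% reached a mean of 10 TPM, among them PDPN at 372, LRRN4 at 245 and ANXA8 at 474 TPM, against 18.2% of endothelial, 25% of muscle and 0.0% of blood markers, and 3 of the 25 mesothelial markers also stand in another list. Trophoblast lists reached as much by this measure (13 of 22 stem cell and cytotrophoblast, 7 of 14 pan-trophoblast and 20 of 41 extravillous genes), so it does not single out mesothelium. The predicted share was 50% or more, and KRT8, KRT18 and KRT19, which trophoblast expresses too, had been seen and were not counted. As means over all libraries, MSLN at 1.58, WT1 at 0.374 and MUC16 at 0.0 TPM were low. The test therefore leaves mesothelium-like cells open as a source. These means hide group differences: in TSC, ST and EVT, MSLN was at 0.0, 3.74 and 1.01 TPM and WT1 at 0.0, 0.734 and 0.389 TPM. Other markers were highest in TSC, such as PDPN (527, 216 and 373 TPM) and LRRN4 (445, 180 and 109 TPM). Over all 25 markers the mean log2(TPM + 1) was 4.19, 4.87 and 4.34. Whether the list differs between groups was not tested. Mesothelium was the only cell type tested as a source, so other sources of mesenchymal transcripts stay open too. No sort or gate is described that would remove such cells, and no group of the design gives a biological explanation, so none was tested.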
